A study of Mus musculus with 9 samples.

How the data were processed

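Polyadenylated RNA was sequenced from pools of 60 mouse embryos (B6D2F1 background), with 3 libraries each for embryos injected with control siRNA (NC), Hdac1 and Hdac2 siRNA (Hdac1/2 cKD) and Sin3a siRNA (Sin3a KD). Per the submitters' processing notes, reads were assigned to transcripts and counted with Salmon, normalised with DESeq2 and placed on build GRCm38; the versions and the transcript annotation are not given in the sources used here. The signal values that the authors deposited are gene-level read counts divided by DESeq2 normalisation factors, called normalised counts in the text. In each library between 59.2% and 72.9% of the low values lay within 0.1 of a whole multiple of 1 step, and since the rest lay between steps the whole reads could not be recovered. From that step the depth was estimated at 8.40 M reads in the shallowest library (NC replicate 3) and 16.8 M in the deepest (NC replicate 1), and normalised counts added up to 11.9 M to 13.5 M per library. Per the labels, RFP and GFP RNA was added before extraction, but a search of the gene names found 0 entries for either, so no scaling to added RNA was made and a change in total RNA per embryo cannot be seen. The table held 20087 named genes and 1 line without a name, which carried 0.00543% to 0.00896% of each library's total and was left out. Gene coordinates were taken from the GENCODE vM21 annotation, in which 19072 symbols (94.9%) matched exactly 1 gene.

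Groups, comparisons, gene lists, filters, the rule for naming genes and most alternatives were fixed before the data were examined. Genes with a value of at least 10 in at least 3 of the 9 libraries were tested, 13343 in all. Values were taken as log2(value + 1), which understates the change of genes with low values, and all 9 libraries were fitted together with 1 mean per group in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom and moderated variances (trend and robust). The p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and genes with an adjusted p below 0.05 were called. The comparisons were Hdac1/2 cKD against NC, Sin3a KD against NC and Hdac1/2 cKD against Sin3a KD. NC serves in 2 of them, so their changes are not independent. Sequencing lanes, read from the library descriptions, differed between groups (NC on lanes 5, 2 and 3, Hdac1/2 cKD on 2, 2 and 3, Sin3a KD on 4, 3 and 3). Lane was therefore also fitted as a factor, and medians of called genes are given within lanes that hold both groups. NC replicate 1 and Sin3a KD replicate 1 are alone on their lanes, so with lane as a factor they add nothing to the comparisons. That fit thus compares the same libraries as the fit that leaves both out, and a lower count in it need not come from lane. NC replicate 3 is the only NC library on lane 3. Principal components of the tested genes took up 26.5%, 21.1% and 14.2% of the variance. On the first, NC replicate 3 stood apart at -96.6, with the other NC libraries at -16.8 and -20.7, Hdac1/2 cKD at 41.3 to 50.3 and Sin3a KD at -6.65 to 1.54. On the second, NC replicate 3 was at -58.5 and the other NC libraries at 2.27 and 39.1.

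In all, 32 gene lists with 751 entries were written from general knowledge, of which 722 entries were in the file and 606 were tested. The 28 lists with at least 5 tested members went into camera with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. For some lists the estimate lay below the preset value (0.0029 for the Sin3 complex, -0.033 for glycolysis). A higher adjusted p with an estimated correlation therefore need not come from correlation between the genes. Called members were also counted after adjusting over the list alone. Genes named in the text come from a rule with 3 parts. It takes the targets, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 50 and groups that do not overlap, predicted gene models left out, and from each list up to 4 called members with the lowest adjusted p, or up to 2 members where none passed. The examples shown were chosen from these after their values were seen, preferring calls kept when any library was left out.

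The fit was tested on simulated data drawn from the real genes' levels and spread, in which 12909 genes passed the filter. In each knockdown 100 genes were changed at each size. Far more were called in the real data, which moves the adjusted threshold, so the shares recovered there may differ. Among changed genes of Hdac1/2 cKD against NC, 34.0% were recovered at a log2 change of 1 and 71.0% at 2, and 4.55% of calls were of unchanged genes. In Sin3a KD against NC the shares were 36.0% and 73.0%, with 1.80% of calls of unchanged genes, and in Hdac1/2 cKD against Sin3a KD 38.0% and 74.0%, with 6.28%. A gene that did not pass can therefore have changed. Likeness between the knockdowns was set against 20 simulations of unchanged groups with shared controls. Every way to split the 6 libraries of a comparison into 2 groups of 3 was also fitted. In all, 23 alternatives were run, among them other pseudocounts, filters, scalings, variance settings, lane or replicate number in the fit, and each library left out. The sums, word searches and stretch comparisons of the closing section were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.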

Results

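Gene expression was measured by RNA sequencing in mouse embryos of the B6D2F1 background that had been injected as zygotes with small interfering RNA (siRNA, a short double-stranded RNA that lowers the level of the messenger RNA it matches). The 3 groups received a nonspecific control siRNA (NC), siRNA against the histone deacetylase genes Hdac1 and Hdac2 (labelled Hdac1/2 cKD), or siRNA against Sin3a, the scaffold of a corepressor complex that holds both deacetylases (labelled Sin3a KD). Embryos were collected at E2.75, around the morula stage before the blastocyst cavity forms. For each of 3 libraries per group, 60 embryos were pooled. The study's title places its question in the overlapping roles of both deacetylases in lineage development and in DNA methylation before implantation. The table held normalised counts for 20087 named genes, of which 13343 reached a value of 10 in at least 3 of the 9 libraries and were tested. The share of genes listed at 0 was highest in NC replicate 3, at 28.4%, and this control library also stood apart on the first principal component (-96.6, against -16.8 and -20.7 for the other NC libraries). Replicates correlated across genes with Pearson's r of 0.908 to 0.942 in NC, 0.948 to 0.959 in Hdac1/2 cKD and 0.948 to 0.964 in Sin3a KD, where genes are not independent replicates. Group values below are normalised counts as mean ± SD (n = 3), the first group of each comparison first. Coordinates refer to GRCm38, and log2 stands for the log2 fold change with its standard error (SE). The labels do not say that the replicates came from separate collections, so the p-values measure the spread between these samples only, which may be technical.

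The targeted genes were lower in the libraries labelled for them. Hdac1 (chromosome 4, 129516104 to 129542713, reverse strand) stood at 943 ± 152 (SD, n = 3) in Hdac1/2 cKD against 5569 ± 661 in NC, which was 16.9% of the NC mean. Its values were 1052, 1007 and 769.6 in the Hdac1/2 cKD libraries and 6245, 4925 and 5536 in the NC libraries. Hdac2 (chromosome 10, 36974544 to 37001889, forward strand) stood at 305 ± 97.2 (SD, n = 3) against 2286 ± 241, or 13.3% of NC. Its values were 193, 350.3 and 371 in Hdac1/2 cKD and 2347, 2020.3 and 2492 in NC. Sin3a (chromosome 9, 57072040 to 57128366, forward strand) stood at 431 ± 83.6 (SD, n = 3) in Sin3a KD against 1484 ± 283 in NC, or 29.0% of NC. Its values were 354, 520.1 and 418 in Sin3a KD and 1779, 1215 and 1459 in NC. The change against NC was log2 -2.57, SE 0.21, adjusted p = 2.21e-05 for Hdac1. It was log2 -2.95, SE 0.20, adjusted p = 2.90e-06 for Hdac2 and log2 -1.78, SE 0.17, adjusted p = 0.000652 for Sin3a. All 3 libraries of the treated group lay below all 3 NC libraries for each target, and each call was kept in every alternative setting. Hdac1 shares long stretches of sequence with the predicted gene Gm10093, so the division of reads between them is uncertain.

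Hdac1 was also lower in Sin3a KD, at 1910.4 ± 639 (SD, n = 3) with values of 1333, 2597 and 1802 (log2 -1.59, SE 0.21, adjusted p = 0.00297). With moderation that used neither a trend nor robust variances this adjusted p came to 0.0523, whereas it stayed below 0.05 in the other settings. Hdac2 in Sin3a KD, at 2060.1 ± 67.6 with values of 2136, 2036 and 2008, did not pass the test (log2 -0.15, SE 0.20, adjusted p = 0.711). Sin3a in Hdac1/2 cKD was 2044 ± 175 with values of 1990.2, 2239.7 and 1903, and did not pass (log2 0.48, SE 0.17, adjusted p = 0.0693), although with libraries scaled to equal totals its adjusted p was 0.0211. It was 0.0346 without NC replicate 1, 0.0330 with lane as a factor and 0.0286 without the 2 libraries alone on their lanes.

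**Figure D1:**
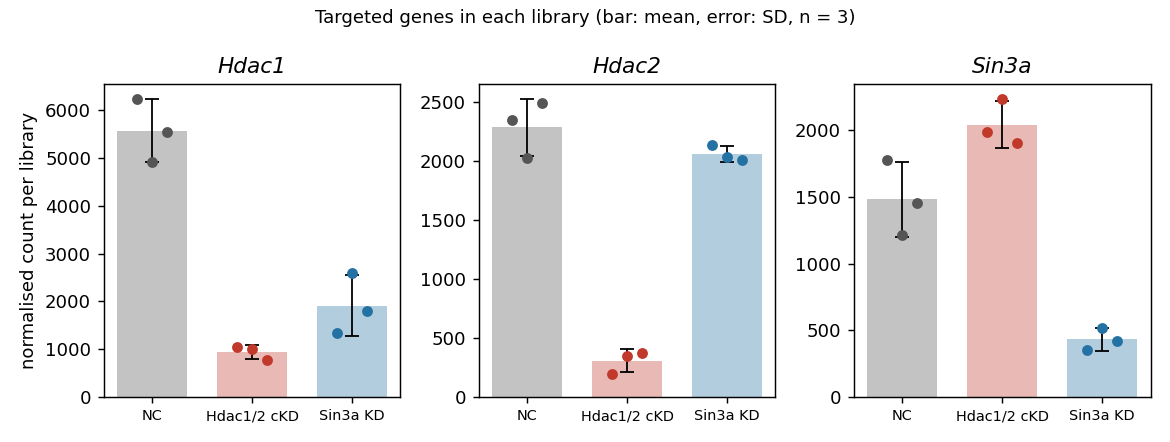
Normalised counts of Hdac1, Hdac2 and Sin3a (vertical axes, counts per library, starting at 0) in the 3 groups; bars are means, error bars SD over 3 libraries and points single libraries. Hdac1 and Hdac2 were low in Hdac1/2 cKD, Sin3a was low in Sin3a KD, and Hdac1 in Sin3a KD lay between 1333 and 2597, below every NC library.

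In Hdac1/2 cKD against NC, which asks what changes when both deacetylases are lowered, the trophectoderm regulators Cdx2 and Gata3 and the pluripotency genes Tdgf1 and Dppa2 fell. Cdx2 (chromosome 5, 147300805 to 147307270, reverse strand), a homeobox factor of the trophectoderm, the outer layer that forms placenta, fell to 178 ± 25.3 against 1186 ± 256 (SD, n = 3; log2 -2.72, SE 0.19, adjusted p = 2.90e-06). The DNA methylation gene Uhrf1, the growth-promoting cyclin Ccnd1 and the glycolytic gene Ldha rose to several times their NC levels, while Myc fell. In all, 1042 genes were higher and 1041 lower at a Benjamini-Hochberg adjusted p below 0.05 with limma, 15.6% of those tested. A change of at least 1 on the log2 scale was reached by 605 of the higher and 223 of the lower genes.

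Of 18 trophectoderm genes tested, 5 fell, none rose and 13 did not pass; adjusted over the list alone, 5 fell and 2 rose. Besides Cdx2, Gata3 (chromosome 2, 9857078 to 9890034, reverse strand), a transcription factor of the trophectoderm, fell to 376 ± 35.8 against 739.9 ± 57.8 (log2 -0.98, SE 0.15, adjusted p = 0.00084). Fgfr2, a receptor for fibroblast growth factors, fell to 327 ± 90.7 against 1259.6 ± 293 (log2 -1.96, SE 0.21, adjusted p = 7.29e-05). Tfap2c, a transcription factor of the early embryo, fell to 2429 ± 107 against 4272 ± 548 (log2 fold change -0.81, adjusted p = 0.000402). The list as a whole did not pass camera, the competitive test of gene lists (adjusted p = 0.169), and its median change of 0.10 differed in sign from its mean of -0.08 and from the test. Of 23 inner cell mass and pluripotency genes, 10 fell, 2 rose and 11 did not pass; adjusted over the list alone, 11 fell and 2 rose. Tdgf1, a co-receptor for Nodal, fell to 831 ± 111 against 2243 ± 169.8 (log2 -1.44, SE 0.14, adjusted p = 3.31e-05). Klf5 fell to 7461 ± 586 against 11468 ± 752 (log2 -0.62, SE 0.09, adjusted p = 0.000626), and Dppa2 fell to 4584 ± 327 against 8141 ± 995 (log2 -0.82, SE 0.11, adjusted p = 0.000305). This list was lower than other genes (median log2 fold change -0.46, adjusted p = 0.00512), but not when the correlation between its genes was estimated (adjusted p = 0.374 with an estimated correlation). Of 14 primitive endoderm genes, 4 fell, 1 rose and 9 did not pass, or 5 and 3 adjusted over the list alone. Dab2, an endocytic adaptor gene, fell to 1140.3 ± 58 against 2379.8 ± 501 (log2 -1.04, SE 0.16, adjusted p = 0.000732).

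Genes of the Hippo pathway, which reads cell position in the embryo, and of cell polarity and junctions fell more often than they rose. Among 22 Hippo genes, 8 fell and 2 rose over all genes, and 8 fell and 3 rose adjusted over the list alone. Amot, a junctional scaffold of the pathway, fell to 1447 ± 93 against 2861 ± 347 (log2 -0.98, SE 0.13, adjusted p = 0.000394). Wwtr1, which encodes the coactivator TAZ, fell to 899 ± 79.9 against 1542 ± 58.8 (log2 -0.78, SE 0.11, adjusted p = 0.0005). Tead2, a partner of these coactivators, rose to 312 ± 41.5 against 89.8 ± 32.3 (log2 1.83, SE 0.31, adjusted p = 0.00162). Among 23 polarity, junction and cavitation genes, 8 fell and 2 rose, or 9 and 2 adjusted over the list alone. Pard3, a polarity scaffold, fell to 617 ± 153 against 1155 ± 259 (log2 -0.91, SE 0.19, adjusted p = 0.00539), and the claudin gene Cldn4 fell to 4883 ± 60.1 against 7473 ± 1064. Cldn6, another claudin gene of tight junctions, rose to 1079 ± 106 against 209 ± 34.2 (log2 2.37, SE 0.21, adjusted p = 1.48e-05). Neither list passed camera (adjusted p = 0.067 and 0.201), and for the second the mean change of 0.04 differed in sign from the median of -0.16 and the test.

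Of 19 genes of the DNA methylation machinery, 7 rose, 1 fell and 11 did not pass; adjusted over the list alone, 9 rose and 3 fell. Uhrf1 (chromosome 17, 56303321 to 56323486, forward strand), which brings the maintenance methyltransferase to newly replicated DNA, rose to 1461 ± 83.9 against 314 ± 40 (log2 2.22, SE 0.18, adjusted p = 9.06e-06). Dnmt1 (chromosome 9, 20907209 to 20959888, reverse strand), that methyltransferase, rose to 1919 ± 127 against 939 ± 119.8 (log2 1.04, SE 0.13, adjusted p = 0.00024). Gadd45b, linked to DNA repair and demethylation, rose to 262 ± 39.3 against 78.2 ± 11.4. Dnmt3l, a cofactor of de novo methylation, fell to 179 ± 49.5 against 359 ± 58.3 (log2 -1.02, SE 0.23, adjusted p = 0.0088). The list did not pass camera (adjusted p = 0.0929). Among 24 imprinted genes, whose parental copies differ in activity, 6 rose and 2 fell, or 8 and 3 adjusted over the list alone. Sfmbt2 rose to 1256 ± 161 against 199 ± 50.7 (log2 2.67, SE 0.24, adjusted p = 2.21e-05) and Slc38a4 to 493 ± 91.4 against 210.2 ± 25.7 (log2 1.22, SE 0.19, adjusted p = 0.000971). The list itself had an adjusted p = 0.169.

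Of 18 glycolysis genes, 9 rose, none fell and 9 did not pass; adjusted over the list alone, 11 rose. Ldha (chromosome 7, 46841475 to 46855627, forward strand), lactate dehydrogenase A, rose to 2854 ± 541 against 306 ± 96.3 (log2 3.24, SE 0.21, adjusted p = 2.52e-06). Pgk1 rose to 759 ± 70.1 against 287 ± 39.7 (log2 1.40, SE 0.16, adjusted p = 0.000103) and the glucose transporter gene Slc2a1 to 1041 ± 85.4 against 544 ± 67.9 (log2 0.94, SE 0.13, adjusted p = 0.000546). Gapdh rose to 2989.5 ± 274 against 728 ± 204; like Ldha, Pgk1 and other genes of this list it has near-identical copies in the genome, so its level is uncertain. The list passed camera (median log2 fold change 0.78, adjusted p = 6.99e-06) and still passed with an adjusted p = 0.0393 with an estimated correlation. Of 42 cell cycle genes, 8 rose and 4 fell, or 9 and 5 adjusted over the list alone. Ccnd1 (chromosome 7, 144929931 to 144939925, reverse strand), cyclin D1, rose to 2125 ± 346 against 244 ± 55.3 (log2 3.13, SE 0.22, adjusted p = 2.88e-06). Ccnd3 rose to 4675 ± 135 against 2099 ± 301, and the phosphatase gene Cdc25a fell to 1944 ± 153 against 3285 ± 326 (log2 -0.75, SE 0.10, adjusted p = 0.000445). The list did not pass camera (adjusted p = 0.347). Of 8 cyclin-dependent kinase inhibitors, 2 rose, and Cdkn2a reached 182 ± 38.5 against 37.6 ± 17.4 (log2 2.34, SE 0.39, adjusted p = 0.00153). Adjusted over the list alone 3 of them rose. Of 27 p53 target genes, 2 rose and 1 fell, or 1 and 1 adjusted over the list alone. Of 20 apoptosis genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone. Trp53, which encodes p53 itself, was at 1774 ± 115 against 1223 ± 104 (log2 0.54, SE 0.11, adjusted p = 0.00486).

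Among genes of deacetylase complexes, 4 of 11 NuRD genes rose and 1 fell (4 and 2 adjusted over the list alone), with Gatad2a at 2911 ± 237 against 1595 ± 126 (log2 0.87, SE 0.11, adjusted p = 0.000329). Of 17 Sin3 complex genes 3 rose in both counts. Of 9 CoREST genes, 2 rose and 1 fell in both counts, with Zmym2 at 1239.7 ± 71.6 against 694 ± 36.9 (log2 0.84, SE 0.12, adjusted p = 0.000466). None of 12 histone acetyltransferase genes passed, where the lowest adjusted p was 0.0827 for Kat8, and the single call among 14 other deacetylase genes was not kept adjusted over the list alone. None of 75 ribosomal protein genes passed singly. Their list was lower by a median of -0.10 (adjusted p = 0.0256, and adjusted p = 0.7004 with an estimated correlation). That call was lost without NC replicate 1 (0.0702), NC replicate 3 (0.721), Hdac1/2 cKD replicate 1 (0.0759) and Hdac1/2 cKD replicate 2 (0.111). It was also lost with equal totals (0.347), lane as a factor (0.178), a mean of at least 50 (0.0989) and without the 2 libraries alone on their lanes (0.0770).

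Among the 10 highest changes by the fixed rule, Padi3, a peptidylarginine deiminase gene, rose to 446 ± 53.6 against 31.6 ± 11 (log2 3.83, SE 0.33, adjusted p = 1.31e-05). Gabbr1 rose to 170.2 ± 33.4 against 11 ± 7.89 (log2 fold change 4.12, adjusted p = 0.00532) and Acaa1b to 156 ± 28.1 against 11.5 ± 12.5 (log2 fold change 4.26, adjusted p = 0.00593). Among the lowest stood Myc (chromosome 15, 61985391 to 61990374, forward strand), a driver of growth and ribosome production, which fell to 89.8 ± 24.2 against 585 ± 112 (log2 -2.71, SE 0.24, adjusted p = 1.58e-05). Akr1b8, an aldo-keto reductase gene, fell to 104 ± 6.78 against 479 ± 26 (log2 -2.20, SE 0.20, adjusted p = 1.63e-05). Groups did not overlap for 33.1% of all tested genes, where chance gives 10%. For called genes the share was 98.9%, which follows largely from their choice by a test on the same libraries. Within lane 2, with 2 Hdac1/2 cKD libraries and 1 NC library, the medians of called higher and lower genes were 1.04 and -0.61. They were 1.19 and -0.64 within lane 3, with 1 library each, where NC replicate 3 was the NC library. These genes were chosen on the same libraries, here and below, so their direction within a lane does not test for a lane effect. With libraries scaled to equal totals, which shifts the median change of all genes by 0.11, the split became 1386 higher and 675 lower, or 67.2% higher instead of 50.02%. Leaving out Hdac1/2 cKD replicate 1, 2 or 3 gave 640.0, 616 and 602 higher and 647, 662 and 665 lower genes. Without NC replicate 3 the counts were 957 and 977. Lower genes numbered 600.0 with moderation lacking trend and robust variances, 657 with lane as a factor and 573 without the 2 libraries alone on their lanes, a fit chosen after the data were seen. Of 102 named calls 70.0 were kept in all 9 fits that left out 1 library, and 79, 80.0 and 78 in the fits just named.

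**Figure D2:**
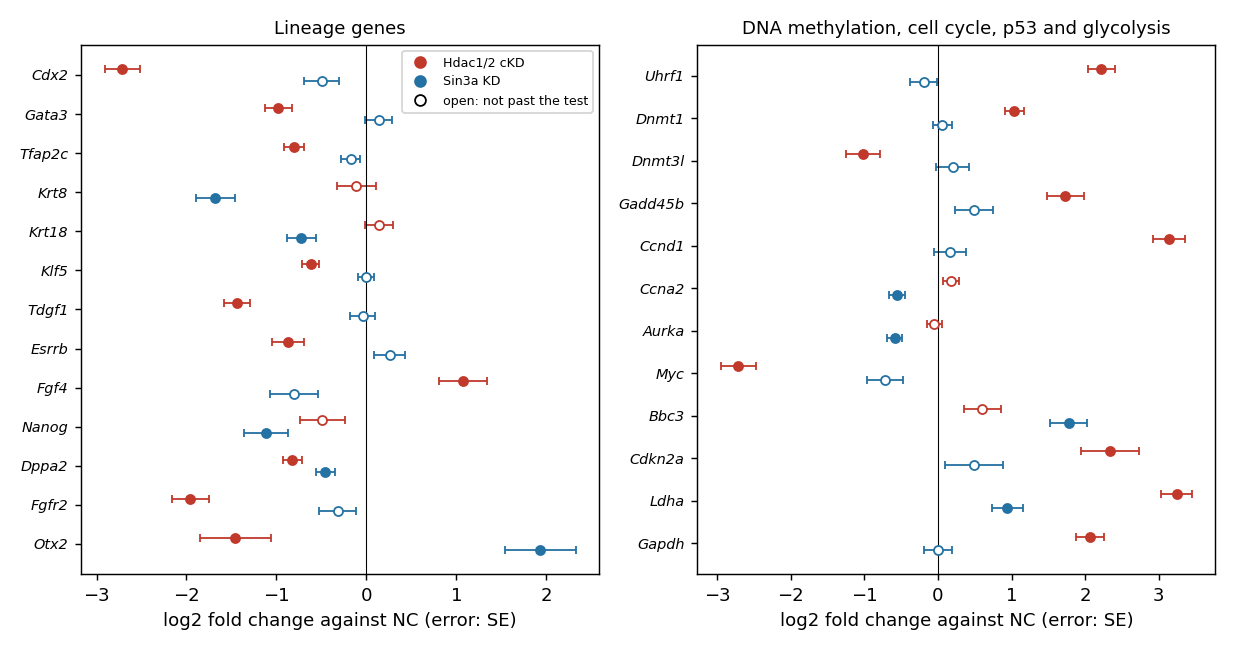
Log2 fold changes against NC (horizontal axes) of lineage genes and of genes of DNA methylation, cell cycle, p53 and glycolysis, in Hdac1/2 cKD (red) and Sin3a KD (blue); points are limma estimates, error bars standard errors and open points did not pass the test. The genes were picked for display from those named by the fixed rule in any comparison. Cdx2 stands at -2.72 and Ccnd1 at 3.13 in Hdac1/2 cKD, and Krt8 at -1.68 in Sin3a KD.

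Sin3a KD against NC asks what changes when the scaffold of the Sin3 complex is lowered. The deacetylase gene Hdac5 and the keratin gene Krt8 fell and the p53 target gene Bbc3 rose. In these libraries Sin3a stood at 29.0% and Hdac1 at 34.3% of the NC mean. Changes in this comparison can therefore not be assigned to Sin3a apart from Hdac1. Krt8 (chromosome 15, 101996698 to 102004482, reverse strand), a keratin of the first epithelium of the embryo, fell to 472 ± 88.2 against 1552 ± 508 (SD, n = 3; log2 -1.68, SE 0.21, adjusted p = 0.00222). Bbc3 (chromosome 7, 16308393 to 16318205, forward strand), which encodes the p53-induced cell death protein PUMA, rose to 1209.5 ± 250.1 against 359.7 ± 109.8 (log2 1.78, SE 0.25, adjusted p = 0.00297). The calls of Krt8 and Bbc3 did not hold in every fit. With moderation lacking trend and robust variances both had an adjusted p of 0.0523, Krt8 had 0.0510 without the 2 libraries alone on their lanes, and Bbc3 had 0.0502 with lane as a factor. In all, 480.0 genes were higher and 582 lower, 7.96% of those tested, and 178 and 153 of them changed by at least 1 on the log2 scale.

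Of 27 p53 targets, 9 rose, none fell and 18 did not pass; adjusted over the list alone, 10 rose and 1 fell. Dcxr rose to 552 ± 129 against 155 ± 63.2 (log2 1.89, SE 0.35, adjusted p = 0.0077). The list was higher than other genes (median log2 fold change 0.35, adjusted p = 0.000724), but not when the correlation was estimated (adjusted p = 0.658 with an estimated correlation) or with lane as a factor (0.289). Bcl2l11, the cell death gene BIM, rose to 663 ± 93.7 against 299 ± 64.6 (log2 1.16, SE 0.19, adjusted p = 0.00502) and was the 1 of 20 apoptosis genes that passed, in both counts. Of 42 cell cycle genes, 5 fell and none rose; adjusted over the list alone, 8 fell and 2 rose. Aurka, a mitotic kinase gene, fell to 3242 ± 122 against 4893 ± 623 (log2 -0.59, SE 0.10, adjusted p = 0.00621). Ccna2, cyclin A2, fell to 3421 ± 161 against 5060.4 ± 755 (log2 -0.55, SE 0.11, adjusted p = 0.00947). Neither passed with moderation lacking trend and robust variances (0.0671 for Aurka, 0.0799 for Ccna2), with lane as a factor (0.0504 and 0.107) or without the 2 libraries alone on their lanes (0.103 and 0.124). The list was lower (median -0.18, adjusted p = 0.00690, and adjusted p = 0.197 with an estimated correlation), but not with equal totals (0.0614). Of 8 cyclin-dependent kinase inhibitors 1 rose, or 2 adjusted over the list alone, with adjusted p = 0.0494 for the list and adjusted p = 0.5002 with an estimated correlation. That list call was lost without NC replicate 1 (0.104), NC replicate 3 (0.0908), Sin3a KD replicate 1 (0.176) and each Hdac1/2 cKD replicate (0.0583, 0.0570 and 0.0523). It was also lost with a pseudocount of 0.5 (0.0508), TMM scaling (0.0512), equal totals (0.116), lane as a factor (0.239) and without the 2 libraries alone on their lanes (0.273).

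Of 18 trophectoderm genes, 3 fell and none rose in both counts. Besides Krt8, Lrp2, an endocytic receptor gene, fell to 2096 ± 228 against 3424 ± 241 (log2 -0.71, SE 0.10, adjusted p = 0.00297). Krt18, the partner keratin of Krt8, fell to 372 ± 31.2 against 620.2 ± 108 (log2 -0.72, SE 0.16, adjusted p = 0.016), a call lost without NC replicate 1, NC replicate 3 or Sin3a KD replicate 3, where the highest adjusted p was 0.0713. The list had a median change of 0.00, a mean of 0.03 and a test of the opposite sign (adjusted p = 0.223). Of 23 inner cell mass and pluripotency genes, 2 fell, or 4 with 1 rising adjusted over the list alone. Nanog, a core pluripotency factor, fell to 628 ± 229 against 1335 ± 369.6 (log2 -1.12, SE 0.25, adjusted p = 0.0194), but not without NC replicate 3, Sin3a KD replicate 1 or Sin3a KD replicate 3, where the adjusted p reached 0.0766. Of 14 primitive endoderm genes 3 rose and none fell, or 3 and 2 adjusted over the list alone. These 3 encode basement membrane proteins. Col4a1 rose to 2887 ± 150.2 against 1612 ± 373 (log2 0.87, SE 0.15, adjusted p = 0.0063) and Col4a2 to 2296 ± 351 against 1071 ± 299 (log2 1.13, SE 0.19, adjusted p = 0.00542). Lamb1 rose to 1551 ± 205 against 858 ± 148 (log2 0.86, SE 0.15, adjusted p = 0.0063). Among 22 Hippo genes 3 rose and 3 fell, or 4 and 5 adjusted over the list alone. Wwc1, the upstream regulator KIBRA, fell to 194 ± 37.6 against 622 ± 219.7 (log2 -1.64, SE 0.23, adjusted p = 0.00297). Of 23 polarity genes 2 fell in both counts.

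Of 17 Sin3 complex genes, 5 rose, or 5 with 1 falling adjusted over the list alone. Sap30 rose to 1308 ± 272 against 562 ± 136 (log2 1.22, SE 0.19, adjusted p = 0.0035) and Ing1, a chromatin reader of the complex, to 1448 ± 221 against 728 ± 67.9 (log2 0.98, SE 0.15, adjusted p = 0.0035). The list was higher (median 0.14, adjusted p = 0.0153, and adjusted p = 0.197 with an estimated correlation), but not without the 2 libraries alone on their lanes (0.0678). Hdac5, another deacetylase gene, fell to 163 ± 49.4 against 622 ± 39.2 (log2 -1.97, SE 0.21, adjusted p = 0.000865) and was the 1 of 14 other deacetylase genes to pass in both counts. Of 18 glycolysis genes, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone. Tpi1 rose to 820.4 ± 56.5 against 249.5 ± 119 (log2 1.81, SE 0.27, adjusted p = 0.00355) and Slc2a3 to 7859.9 ± 437 against 4091 ± 1222 (log2 0.98, SE 0.18, adjusted p = 0.00953). Pgam1 fell to 2796 ± 576 against 4862 ± 670.0 (log2 -0.81, SE 0.14, adjusted p = 0.00542). The list passed (median 0.61, adjusted p = 0.000724, and adjusted p = 0.146 with an estimated correlation). Ribosomal protein genes were lower as a list (median -0.12, adjusted p = 3.72e-05, and adjusted p = 0.705 with an estimated correlation). Singly 3 of 75 fell in both counts, among them Rpl3 at 4539 ± 825 against 9799 ± 2234 (log2 -1.10, SE 0.18, adjusted p = 0.00542). The list call was lost without NC replicate 3 (0.0908), and near-identical copies in the genome make the levels of ribosomal protein genes uncertain. None of the 19 DNA methylation genes and none of the 11 NuRD genes passed by limma, in a comparison where 3193 genes had an unadjusted p below 0.05.

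Among the 10 highest changes by the fixed rule, Acot1 rose to 108 ± 33.8 against 13.5 ± 13.2 (log2 3.24, SE 0.56, adjusted p = 0.00553). Btg3, an antiproliferative gene, rose to 284 ± 58.5 against 67 ± 34.6 (log2 2.21, SE 0.38, adjusted p = 0.00586). Otx2, a homeobox factor of head and epiblast, rose to 401 ± 54.2 against 115 ± 67.4 (log2 1.93, SE 0.39, adjusted p = 0.0112), with an adjusted p of 0.0542 without Sin3a KD replicate 3. Among the lowest stood Snrpd3, a splicing core protein gene, at 278 ± 118 against 1259 ± 394 (log2 -2.21, SE 0.28, adjusted p = 0.00261). Fgf3 fell to 40.4 ± 16.7 against 159 ± 12.8 (log2 -2.05, SE 0.35, adjusted p = 0.00542) and Ints7, an Integrator subunit gene, to 360.0 ± 207 against 1364 ± 279 (log2 -2.05, SE 0.33, adjusted p = 0.0078). Groups did not overlap for 27.1% of all tested genes, where chance gives 10%, and for 99.5% of called genes, which the test selects for. Within lane 3, with 2 Sin3a KD libraries and NC replicate 3 as the 1 NC library, the medians of called genes were 0.93 and -0.73. Equal totals gave 741 higher and 425 lower genes, or 63.6% higher instead of 45.2%. The counts were small in some fits. Moderation without trend or robust variances gave 17 higher and 19 lower, lane as a factor 61 and 33, and a fit of these 2 groups alone 287 and 362. A fit without the 2 libraries alone on their lanes, chosen after the data were seen, gave 25 and 24. With lane as a factor those 2 libraries add nothing to the comparison, so it and this fit are not separate checks. Leaving out Sin3a KD replicate 1 or 3 gave 128 and 122 higher and 209 and 215 lower genes. NC replicate 1 gave 288 and 300.0, NC replicate 3 gave 313 and 373, and NC replicate 2 gave 741 higher genes. Of 79 named calls, 38 were kept in all 9 fits that left out 1 library, 5 in the fit lacking trend and robust variances, 17 with lane as a factor and 10 without the 2 libraries alone on their lanes. The 5 are Sin3a, Hdac5, Ppp1r14a, Galc and Stat2. Of the genes given above, Sin3a, Hdac1, Hdac5, Wwc1, Btg3 and Snrpd3 passed in the last 2 of these fits, Krt8, Sap30, Ing1, Col4a2, Slc2a3 and Otx2 with lane as a factor only, and Bbc3 only without the 2 libraries.

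**Figure D3:**
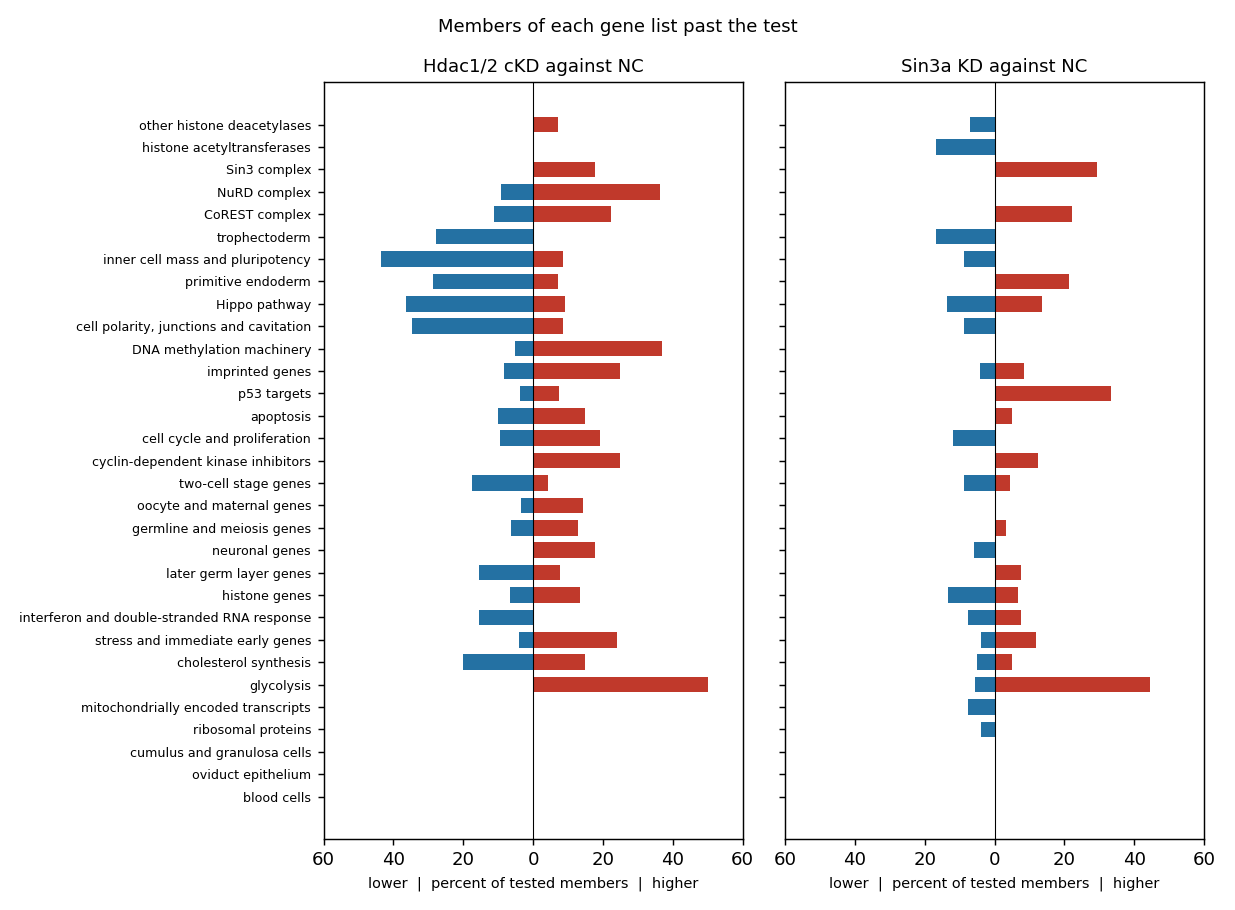
Percent of the tested members of each fixed gene list that passed the test as higher (red, to the right) or lower (blue, to the left) against NC, in Hdac1/2 cKD and in Sin3a KD. In Hdac1/2 cKD, 10 of 23 inner cell mass and pluripotency genes were lower and 9 of 18 glycolysis genes higher; in Sin3a KD, 9 of 27 p53 targets were higher.

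Setting the knockdowns against each other, which tests where they differ, gave lower values of Cdx2, Gata3 and Tdgf1 and higher values of Ccnd1, Ccna2 and Uhrf1 in Hdac1/2 cKD. Cdx2 stood at 178 ± 25.3 against 839 ± 174 (SD, n = 3) in Hdac1/2 cKD against Sin3a KD (log2 -2.22, SE 0.19, adjusted p = 1.32e-05). Ccnd1 stood at 2125 ± 346 against 274 ± 64.8 (log2 2.97, SE 0.22, adjusted p = 3.52e-06), and Otx2 at 39.8 ± 18.8 against 401 ± 54.2 (log2 -3.39, SE 0.39, adjusted p = 0.000118). In this comparison 1133 genes were higher and 1171 lower in Hdac1/2 cKD, and 545 and 341 of them differed by at least 1 on the log2 scale. Hdac1 itself was lower in Hdac1/2 cKD than in Sin3a KD (log2 -0.98, SE 0.21, adjusted p = 0.00749), as was Hdac2 (log2 -2.81, SE 0.20, adjusted p = 4.01e-06), and Sin3a was higher (log2 2.26, SE 0.17, adjusted p = 3.52e-06).

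Of 23 inner cell mass and pluripotency genes, 11 were lower and 3 higher in Hdac1/2 cKD, or 11 and 4 adjusted over the list alone. Tdgf1 stood at 831 ± 111 against 2195 ± 376 (log2 -1.39, SE 0.14, adjusted p = 4.14e-05). Esrrb, an orphan nuclear receptor gene of pluripotent cells, stood at 1383 ± 214 against 3024 ± 442 (log2 -1.13, SE 0.17, adjusted p = 0.000769). Fgf4, a growth factor made by inner cells, was higher, at 419 ± 80.8 against 116 ± 37 (log2 1.88, SE 0.26, adjusted p = 0.000408). The mean of 0.07 for this list differed in sign from its median of -0.37 and from the test, which it did not pass (adjusted p = 0.0742). Of 18 trophectoderm genes, 5 were lower and 3 higher, or 6 and 4 adjusted over the list alone. Gata3 was lower at 376 ± 35.8 against 818 ± 105 (log2 -1.12, SE 0.15, adjusted p = 0.000295) and Lrp2 higher at 4192 ± 195 against 2096 ± 228 (log2 1.00, SE 0.10, adjusted p = 4.73e-05). Of 14 primitive endoderm genes, 6 were lower and 1 higher, or 6 and 3 adjusted over the list alone. The receptor gene Pdgfra stood at 73.6 ± 19.5 against 205 ± 26.9 (log2 -1.49, SE 0.26, adjusted p = 0.00178). Among 22 Hippo genes 6 were lower and 3 higher in both counts, with Wwtr1 at 899 ± 79.9 against 1977 ± 90.8 and Wwc1 at 804 ± 149 against 194 ± 37.6.

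Of 42 cell cycle genes, 13 were higher and 2 lower, or 16 and 2 adjusted over the list alone. Ccna2 stood at 5668 ± 191 against 3421 ± 161 (log2 0.73, SE 0.11, adjusted p = 0.000569) and the mitotic kinase gene Plk1 at 2852 ± 58.7 against 1972 ± 39 (log2 0.53, SE 0.09, adjusted p = 0.00138). The list passed with an adjusted p = 0.00381, and adjusted p = 0.289 with an estimated correlation. Of 19 DNA methylation genes, 6 were higher and 1 lower, or 8 and 1 adjusted over the list alone. Uhrf1 stood at 1461 ± 83.9 against 279 ± 63.9 (log2 2.41, SE 0.18, adjusted p = 4.53e-06) and Dnmt1 at 1919 ± 127 against 979 ± 116 (log2 0.97, SE 0.13, adjusted p = 0.000302). This list passed with adjusted p = 0.00955, and had an adjusted p = 0.289 with an estimated correlation and 0.0660 with lane as a factor. Mitochondrially encoded transcripts, of which 2 of 13 were higher in both counts, passed as a list (adjusted p = 0.0237, and adjusted p = 0.596 with an estimated correlation), but not without Sin3a KD replicate 1 (0.122), with lane as a factor (0.209) or without the 2 libraries alone on their lanes (0.132). They made up 4.08 ± 0.0623% of the normalised counts in Hdac1/2 cKD, 3.50 ± 0.348% in Sin3a KD and 3.61 ± 0.380% in NC (SD, n = 3). Of 27 p53 targets 6 were lower and 3 higher in both counts. Bbc3 stood at 540.3 ± 153 against 1209.5 ± 250.1 (log2 -1.18, SE 0.25, adjusted p = 0.00671) and the death effector gene Perp at 479 ± 101 against 1351 ± 132 (log2 -1.51, SE 0.17, adjusted p = 8.40e-05).

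Of 11 NuRD genes 5 were higher and 1 lower in both counts, with Gatad2a at 2911 ± 237 against 1517 ± 158 (log2 0.94, SE 0.11, adjusted p = 0.000151). Of 18 glycolysis genes 5 were higher and 1 lower, or 6 and 2 adjusted over the list alone, where Hk2, hexokinase 2, was lower at 1353 ± 209 against 2132 ± 215 (log2 -0.66, SE 0.14, adjusted p = 0.00462). Neither list passed camera (adjusted p = 0.189 and 0.113).

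Groups did not overlap for 39.7% of all tested genes, where chance gives 10%, and for 99.3% of called genes, which the test selects for. Within lane 3, with 1 Hdac1/2 cKD and 2 Sin3a KD libraries, the medians of called genes were 0.93 and -0.69. Equal totals gave 1223 higher and 1109 lower genes, or 52.4% higher instead of 49.2%. Lane as a factor gave 450.0 higher and 552 lower genes, and leaving out Hdac1/2 cKD replicate 1 or 2 gave 753 and 715 higher and 771 and 792 lower. Leaving out Sin3a KD replicate 1 gave 744 higher and 683 lower genes, and a fit without the 2 libraries alone on their lanes gave 722 and 668. Moderation lacking trend and robust variances gave 775 lower genes. Of 116 named calls, 92 were kept in all 9 fits that left out 1 library, 96 in the fit lacking trend and robust variances, 82 with lane as a factor and 98 without the 2 libraries alone on their lanes.

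Both knockdowns were compared with the same NC libraries, so part of any likeness between their changes comes from shared values. The log2 fold changes of both comparisons correlated across genes with r = 0.48, where simulated unchanged groups set against the same controls gave 0.50. The covariance was 0.292 against 0.131 in the simulations, a difference of 0.161. The simulations gave all groups the same spread for a gene, while NC replicates correlated least (r of 0.908 to 0.942). A wider spread in NC would bring more covariance from shared controls, so the difference may be overstated. Called genes that were higher in both numbered 170.0, where independent lists would give 37.5, and genes lower in both numbered 158 (independent lists 45.4). Another 28 were higher in Hdac1/2 cKD and lower in Sin3a KD (independent lists 45.5), and 21 the reverse (independent lists 37.4). Among the genes that rose in both was Sfmbt2, with log2 fold changes of 2.67 and 1.48. Among those that fell in both were Hdac1 and Amot, the second with -0.98 and -0.66. Amot did not pass in Sin3a KD without Sin3a KD replicate 3 (adjusted p = 0.0562). The simulated groups gave 0 such genes because they yield next to no calls, and independent lists leave out the shared controls, so neither says how many genes shared controls alone would bring. The 3 NC libraries cannot be split so that each part keeps 2, and part of these counts may come from the shared controls. Since Hdac1 was lower in both knockdowns, genes called in both cannot be assigned to Sin3a apart from Hdac1. The 328 genes called in the same direction in both became 103 without Sin3a KD replicate 3 and 120.0 without Sin3a KD replicate 1. They became 179 without NC replicate 1, 218 without NC replicate 3, 576 without NC replicate 2, 196 without Hdac1/2 cKD replicate 1 and 182 without Hdac1/2 cKD replicate 3. Without Hdac1/2 cKD replicate 2 the number was 61.0% of 328. They were 14 with moderation lacking trend and robust variances, 35 with lane as a factor and 24 without the 2 libraries alone on their lanes.

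**Figure D4:**
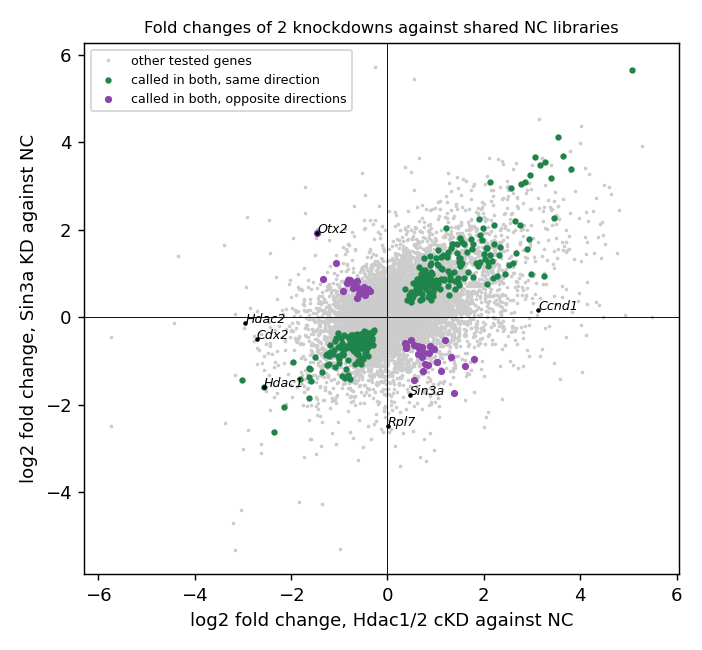
Log2 fold changes of all 13343 tested genes in Hdac1/2 cKD (horizontal axis) and in Sin3a KD (vertical axis), each against the same 3 NC libraries; green points passed in both with the same sign and purple points in both with opposite signs. Both comparisons share their controls, and simulated unchanged groups gave a correlation of 0.50 where 0.48 was observed.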

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

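Fits that share most of their libraries leave little room for a called gene to turn its sign. None called in the fit of the report did so while called in any of the 21 alternatives that refit single genes. Of the values of named genes under these, 2151 of 2360.0 in Hdac1/2 cKD against NC, 1520.0 of 1891 in Sin3a KD against NC and 2319 of 2506 in Hdac1/2 cKD against Sin3a KD kept their direction and side of the threshold. Another 194, 368 and 183 no longer passed, and 14, 2 and 0 newly passed. Some of these refits could change little. Median-of-ratios rescaling of values already normalised with DESeq2 kept all 2083, 1062 and 2304 calls. Leaving out a library of the group not compared leaves the fold change as it was. Such refits raise the shares kept without testing the calls. The cause was not tested for the values below, except that a threshold on size leaves fewer calls by construction. A change of at least 1 on the log2 scale left 605 higher and 223 lower genes, 178 and 153, and 545 and 341 in these comparisons. Scaling to equal totals gave 675 lower genes in Hdac1/2 cKD against NC and 741 higher ones in Sin3a KD against NC, and a fit of the 2 groups alone gave 287 and 362 in the latter. Moderation without trend or robust variances gave 600.0 lower genes in Hdac1/2 cKD against NC, 17 and 19 in Sin3a KD against NC, 775 lower in Hdac1/2 cKD against Sin3a KD and 14 called in both knockdowns. Lane as a factor gave 657 lower, 61 and 33, 450.0 and 552, and 35. A fit without the 2 libraries alone on their lanes, chosen after seeing the data, gave 573 lower, 25 and 24, 722 and 668, and 24, with a correlation between the knockdowns of 0.57. That correlation was 0.41 with a pseudocount of 8 and 0.42 with a mean of at least 50. Lists called numbered 5 in Hdac1/2 cKD against NC and 5 in Hdac1/2 cKD against Sin3a KD without a filter, 5 in the latter with a mean of at least 50, and 1, 0 and 0 with an estimated correlation.

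Leaving out 1 library at a time gave 602 to 1115 higher and 647 to 1060.0 lower genes with 2 to 4 lists in Hdac1/2 cKD against NC. It gave 122 to 741 and 209 to 796 with 5 to 7 lists in Sin3a KD against NC. It gave 715 to 1372 and 683 to 1387 with 2 to 6 lists in Hdac1/2 cKD against Sin3a KD. Genes called in both numbered 103 to 576, and the correlation across all tested genes was 0.45 to 0.60. The targets stayed at -2.65 to -2.43 (Hdac1), -3.12 to -2.66 (Hdac2) and -1.93 to -1.64 (Sin3a). Values that turned their sign belong to genes that did not pass. Foxl2 in Hdac1/2 cKD against Sin3a KD went from -0.29 to 0.58 with lane as a factor, 0.093 without the 2 libraries alone on their lanes and 0.093 without Sin3a KD replicate 1, with -0.71 to 0.30 over all libraries left out. Ovgp1 in Hdac1/2 cKD against NC ran from -0.089 to 1.06 and Ptprc in Sin3a KD against NC from -0.22 to 0.85, both lowest without NC replicate 3.

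The replicate number was also fitted as a replicate block, though same-numbered libraries deviated together only with r of -0.02 to 0.06 over 9 pairs. As a hint from the data, 7 of 9 libraries were closest to one of their own number. The block gave 1057 higher and 1083 lower genes in Hdac1/2 cKD against NC, 476 and 570.0 in Sin3a KD against NC, 1138 and 1234 in Hdac1/2 cKD against Sin3a KD, and 314 called in both. Planned fits of whole reads with edgeR and DESeq2 and scaling to the added RNA were not run, since neither whole reads nor entries for the added RNA were found. Depth ran from about 8.40 M to 16.8 M reads, and what it limits was not tested.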

Other observations

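Among the germline and neuronal genes called in Hdac1/2 cKD against NC, more rose than fell. Of 31 and 17 tested, 25 and 14 did not pass. Over all tested genes 15.6% were called, and 605 higher against 223 lower genes changed by at least 1 on the log2 scale. Of 31 germline and meiosis genes, 4 rose and 2 fell against NC in both counts, all genes and adjusted over the list alone. The RNA helicase gene Ddx4, a marker of germ cells, rose to 430.3 ± 17.1 against 169 ± 43.1 (log2 1.38, SE 0.22, adjusted p = 0.00115), and Mael, needed to silence transposons, to 396 ± 169.6 against 145 ± 20.5 (log2 1.37, SE 0.26, adjusted p = 0.0037), while Piwil2 fell to 620.4 ± 69.4 against 1052 ± 60.5 (log2 -0.77, SE 0.15, adjusted p = 0.00391). In Sin3a KD 1 rose, and none adjusted over the list alone. Of 17 neuronal genes 3 rose in Hdac1/2 cKD, among them Elavl3 to 477 ± 57.8 against 191 ± 13.3 (log2 1.31, SE 0.20, adjusted p = 0.000853), and 1 fell in Sin3a KD. Against Sin3a KD, 5 were higher in Hdac1/2 cKD, or 6 adjusted over the list alone. Of 28 oocyte and maternal genes 4 rose and 1 fell in Hdac1/2 cKD, where Khdc3 was at 6014 ± 752 against 10324 ± 737 (log2 -0.78, SE 0.11, adjusted p = 0.000453), and none passed in Sin3a KD. Of 23 genes of the 2-cell stage 1 rose and 4 fell in Hdac1/2 cKD, and 1 rose and 2 fell in Sin3a KD, where Tmem92 fell (log2 -0.63, SE 0.12, adjusted p = 0.0077). In both comparisons the mean of this list (0.14 and 0.17) differed in sign from its median (-0.20 and -0.10) and from the test. Of 13 later germ layer genes 1 rose and 2 fell in Hdac1/2 cKD, and 1 rose in Sin3a KD. In the first, the median of 0.22 and mean of 0.34 differed in sign from the test (adjusted p = 0.973). None of these lists passed camera against NC (lowest adjusted p = 0.1598 for germline genes in Hdac1/2 cKD).

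Of 20 cholesterol synthesis genes, 3 rose and 4 fell in Hdac1/2 cKD, or 4 and 4 adjusted over the list alone. Srebf2, the master regulator of this pathway, rose to 454 ± 119.6 against 116 ± 45.7 (log2 2.03, SE 0.35, adjusted p = 0.00211), while the pathway enzyme gene Msmo1 fell to 743 ± 119 against 1556 ± 57.3 (log2 -1.08, SE 0.13, adjusted p = 0.000165). In Sin3a KD 1 rose and 1 fell. Of 25 stress and immediate early genes, 6 rose and 1 fell in Hdac1/2 cKD. In Sin3a KD 3 rose and 1 fell, or 5 and 4 adjusted over the list alone, and Ier2 rose in both (log2 0.92 and 0.99). Of 15 histone genes, 2 rose and 1 fell in Hdac1/2 cKD, where H2afz, a variant of histone H2A, rose to 8519 ± 72 against 5452 ± 301 (log2 0.65, SE 0.09, adjusted p = 0.00057). In Sin3a KD 1 rose and 2 fell, and the centromeric histone gene Cenpa fell to 1068 ± 195 against 2014 ± 187 (log2 -0.93, SE 0.14, adjusted p = 0.00319). Of 13 genes of the response to interferon and double-stranded RNA, 2 fell in Hdac1/2 cKD, with Oasl2 at 142 ± 22.9 against 325 ± 48.7, and 1 rose and 1 fell in Sin3a KD, with Stat2 at 134 ± 28.2 against 337 ± 55.7 (log2 -1.33, SE 0.21, adjusted p = 0.00397). Of 24 imprinted genes 2 rose and 1 fell in Sin3a KD, where Impact fell to 372 ± 107 against 770.3 ± 59.1 (log2 -1.09, SE 0.19, adjusted p = 0.00542). With moderation lacking trend and robust variances, 5 of the 79 named Sin3a KD calls were kept. They include Stat2 but not Tmem92, Ier2, Cenpa or Impact. Of 13 mitochondrially encoded transcripts none passed in Hdac1/2 cKD and 1 fell in Sin3a KD. Of 9 CoREST genes 2 rose in Sin3a KD, or 2 with 2 falling adjusted over the list alone. Of 12 histone acetyltransferase genes 2 fell in both counts. The median, mean and test differed in sign for more lists that did not pass. Camera sets a list against the other genes rather than against 0, and scales each change by its spread. Its direction can therefore differ from the sign of the list's own median or mean. In Hdac1/2 cKD against NC, medians and means were 0.02 and -0.15 for interferon genes, -0.06 and 0.03 for acetyltransferases (tests downward), and 0.01 and 0.08 for apoptosis genes (test downward). In Sin3a KD against NC they were -0.12 and 0.26 for histone genes, 0.05 and -0.28 for interferon genes, 0.13 and -0.10 for other deacetylases, 0.09 and 0.08 for polarity genes, 0.05 and 0.04 for neuronal genes, 0.00 and 0.05 for NuRD genes, and 0.00 and 0.00 for acetyltransferases, with downward tests throughout. In Hdac1/2 cKD against Sin3a KD they were -0.07 and 0.03 for acetyltransferases, -0.07 and 0.17 for imprinted genes and -0.04 and 0.29 for germline genes (tests upward). They were -0.15 and 0.17 for oocyte genes, 0.35 and 0.12 for later germ layer genes, 0.18 and 0.13 for interferon genes and 0.04 and 0.16 for cholesterol synthesis genes (tests downward). Of the markers of cumulus and granulosa cells, oviduct and blood, 3 of each list could be tested and none passed against NC over all genes, while 1 oviduct gene was higher in Hdac1/2 cKD adjusted over the list alone. The medians of these lists were 1.42, 0.83 and 0.94 in Hdac1/2 cKD against NC and 0.64, 1.97 and -0.40 in Sin3a KD against NC. Wfdc2 of the oviduct list was at 15.5 ± 10.7 against 1.69 ± 1.97 in Hdac1/2 cKD against NC (adjusted p = 0.0622), and the macrophage marker Cd68 was higher in Hdac1/2 cKD than in Sin3a KD, at 109 ± 6.98 against 39 ± 9.7 (log2 1.48, SE 0.36, adjusted p = 0.0121).

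The patterns below were chosen after seeing the results, and so were the tests made of them. Hdac1 was lower in Sin3a KD, whose siRNA is labelled for Sin3a alone. If Hdac1/2 cKD material had been mixed in, the level of Hdac1 would need a share of 79.1%. Hdac2 would then stand at a log2 fold change of -1.67, but it was measured at -0.15 (SE 0.20), which speaks against mixing of that material. Hdac2 cannot speak to Hdac1 siRNA alone, which stays open. Adding Gm10093, the only gene with a transcript that shares at least 25% of its 25-base stretches with Hdac1, left a change of -1.58 (6260.4 ± 865 in NC and 2167 ± 732 in Sin3a KD). A looser sum over all 358 genes that share any stretch was tried first and gave -0.08, which would have counted for moved reads, and was set aside after that because it takes in unrelated genes through repeats. Transcripts of Sin3a and Hdac1 shared at most 12 bases in a row, fewer than the 19 of an siRNA duplex, while a partial match of the siRNA and an effect of Sin3a on Hdac1 remain open, and rescue with an siRNA-resistant Sin3a would separate them.

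Large rises outnumbered large falls in Hdac1/2 cKD against NC (73.1% of changes of at least 1 on the log2 scale, 66.9% to 83.1% over the alternatives), a pattern tested after it was seen. Against Sin3a KD, without NC in the comparison, the share was 61.5% (56.0% to 64.5% over the alternatives), and in Sin3a KD against NC 53.8% (46.4% to 69.1%). With lane as a factor Sin3a KD against NC had 67.6% beside 73.7% in Hdac1/2 cKD, so unusual NC libraries stay open as part of the cause, while the lowest share under 3 scalings was 71.7%. Median-of-ratios rescaling, 1 of the 3, barely moves values already normalised with DESeq2 (median shift 5.35e-05). Only TMM scaling and equal totals therefore test the scaling. Among genes with a mean of at least 500 the share was 52.2% (60 higher and 55 lower), but with a mean of at least 50 it was still 69.1% (460.0 and 206). Fold changes against values near 0 therefore stay open, as do genes at a low level that became more active.

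The 10 genes that fell most by the rule in Sin3a KD include Rpl7, Map4k1, Snrpd3, Galc and Fgf3, and a shared siRNA match was tested after the list was seen. Rpl7, Map4k1, Syp, Pstpip1 and Hkdc1 lost their call in some fits that left out 1 library. Their highest adjusted p was 0.0642, 0.0595, 0.0617, 0.0980 and 0.115. Snrpd3, Galc, Pklr, Fgf3 and Ints7 kept theirs in all 9 such fits. The longest stretch of bases that any of the 10 shares with Sin3a was 16, below the 19 of a full-length match. Among 16259 words of 7 bases in 12312 genes with 3' untranslated regions, GCCACAC had the lowest score in Sin3a KD (-4.68) and stood in 2 of the 10 genes, which speaks against that word as their common cause. Its permutation p of 0.0110 over 1000 shufflings (0.0529 for the lowest word in Hdac1/2 cKD) does not allow for other word searches that were made and are not reported, and the explanation was narrowed to the lowest word after its value was known. Other words stay open because the siRNA sequences are not given.

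Among all 10 splits of 6 libraries into groups of 3, the real one gave 2083 called genes in Hdac1/2 cKD against NC, and the highest other gave 1. In Sin3a KD against NC these were 1062 and 3, and in Hdac1/2 cKD against Sin3a KD 2304 and 1. In each only 1 split, the real one, reached the real count, and 10 splits are too few for a share below 0.05. The real counts are those of the fit of all 9 libraries. Fits of only the 2 groups compared called 1688, 638 and 2292 of these genes again. Every other split mixes the groups and puts their differences into the spread, so it gives few calls whatever separates the groups. The splits therefore cannot tell treatment from lane. Sin3a KD replicate 2 was nearest to NC among its group in 69.6% of the lower and 57.9% of the higher called genes, against 16.5% and 20.6% for replicate 1 and 13.9% and 21.5% for replicate 3.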
